A study of Rattus norvegicus with 107 samples.

How the data were processed

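The series holds 107 samples: 48 RNA libraries, 29 libraries of the H3K4me3 set and 30 of the H3K9ac set, each set with its controls. Groups come from the sample labels, which give the carcinogen, the oil and the fiber, and 0 per-sample columns were left without a sample. The deposited tables hold raw read counts per library, whole numbers with no normalization seen in them: 1 table per RefSeq transcript accession for RNA and 1 table per region for each mark. The submitters' processing notes name CASAVA 1.8.2, BWA, MACS 1.4.1, bedtools, edgeR and STAR and the builds rn4 and rn5, without saying which tool or build belongs to which table. Each mark's regions are shared by all its libraries, and the table gives the nearest transcript of each region and its distance. A deposited workbook of the authors' edgeR comparisons, per the file headers, holds an adjusted p-value and a log2 fold change per gene or region for 6 terms, with the model not stated. The exception is pectin for H3K9ac, which has an adjusted p-value and no log2 fold change. These comparisons were only counted and compared with the calls made here.

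The RNA table has 11114 entries for 10524 accessions. The 590 repeats carry identical counts and were used once. Symbols for 10123 accessions come from the mark tables, which pair accessions with symbols, and those of 382 more from a RefSeq table of gene names. For 19 accessions no symbol was found. The H3K4me3 table has 40440 entries for 36423 regions, repeated where a region is annotated with several transcripts, and the H3K9ac table has 59817 regions. A region was said to hold a transcript start when the table's start of the nearest transcript lay inside it, as in 8540 H3K4me3 and 8430 H3K9ac regions. The base that coordinates start from is not stated. Each mark table has 1 IgG control column with 0.902 M (mega) counts for H3K4me3 and 0.962 M for H3K9ac. These columns stayed out of every model and serve as background. The IgG column of the H3K4me3 table could belong to more than 1 control sample of the labels, so it is treated as a background level only. IgG held 17.9% and 21.3% of its counts in start regions, against means of 42% and 42.1% in the H3K4me3 and H3K9ac libraries.

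Each assay was analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (minimum count 10, minimum total count 15), TMM normalization, a model with 1 coefficient for each of the 8 groups, and quasi-likelihood tests of 7 contrasts. The RNA model also holds the first digit, 1 or 2, of the animal number as a covariate, since it is unbalanced between groups. The labels do not say what this digit marks, and 16 genes differ by it. The contrasts are the AOM effect over 4 diets, the oil and fiber effects over the other factors, the oil by fiber interaction, fish oil pectin against corn oil cellulose in AOM, AOM against saline on corn oil cellulose, and the difference between the AOM effects on these 2 diets. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Of the features in the tables, 9989 genes, 33539 H3K4me3 regions and 53741 H3K9ac regions passed the filter, with a biological coefficient of variation of 36.7%, 32.3% and 16.5% and 39, 20 and 20 residual degrees of freedom. Levels are CPM, counts scaled to a common library size by the TMM-scaled totals. SE values are the log2 fold change divided by the root of the F statistic.

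Before the data were examined, 22 gene lists of 433 genes were written for pathways, cell types and stress, and were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01, adjusted over the lists of a contrast, and again with an estimated correlation). Whether a mark moves with RNA at the genes called in RNA was tested with limma's fry, which asks whether genes move on balance 1 way and compares them with no other genes. Each gene is represented there by its region with the highest mean count, weighted by the sign of its RNA change, and the 6 two-sided results are adjusted together. Added after the data were seen was a comparison with 10000 random sets of genes not called in RNA that carry the same signs. The text names genes by a rule written in advance: per RNA contrast the 6 largest changes in each direction among called genes with a mean log2 CPM of at least 2 and a gene symbol that is not a placeholder, up to 4 members of each list and a few genes fixed as checks of the diet. For marks the rule takes 4 regions in each direction, and where nothing is called the 3 features with the smallest p. How many libraries show a direction was counted against the median of the matched group.

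The pipeline was tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 features changed. At 1.5, 2 and 4-fold, edgeR recovered 74.6%, 88.1% and 100% of the changed genes in the RNA AOM effect, 67.2%, 94% and 100% in the RNA oil effect and 16.4%, 47.8% and 87.9% in the RNA comparison of the 2 diets in AOM. For H3K4me3 it recovered 25.4%, 61.2% and 98.5% in the AOM effect and 1.5%, 10.4% and 66.7% in the diet comparison, and for H3K9ac 47.8%, 83.6% and 100% and 16.4%, 43.3% and 86.4%. In the RNA AOM simulation 15 of 190 calls were false. Camera called the 1 list changed by 1.5-fold and 0 others, and fry called the changed genes of both marks and not the unchanged ones. The simulated genes vary independently of each other, so these runs cannot show how often correlated genes give false list calls. With the preset correlation, other splits of the real libraries did call lists, as given below.

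Alternatives to these choices were RLE size factors, no filter on low counts, DESeq2 1.42.0, library totals alone for the marks, the RNA model without the covariate, fits over the groups of a contrast only, each mark library left out in turn, and the mean over all regions of a gene. Added after the data were seen were the first axis of a principal component analysis of log2 CPM as a covariate, the first 2 axes, and RNA without 2 or 3 libraries that stand apart. Other splits of the libraries, 60 per result with the real one, were drawn with a fixed seed, within the other 2 factors or between the 2 groups compared. Correlations across libraries were tested with 100000 permutations. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.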

Results

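The series measured RNA and histone marks in colonocytes, the epithelial cells that line the colon, of male rats in a 2 × 2 × 2 design. Rats received azoxymethane (AOM), a chemical that induces colon tumors, at 15 mg/kg in 2 injections 1 week apart, or saline. Their diets held fish oil, a source of n-3 fatty acids, or corn oil, and pectin, a fiber that gut bacteria ferment, or cellulose, which they ferment little. Feeding began 2 weeks before the first injection, and the rats were terminated 10 weeks after it. RNA was sequenced from 48 libraries, 6 in each of the 8 groups. Chromatin with H3K4me3, a mark of active promoters, and chromatin with H3K9ac, a mark of active promoters and enhancers, was sequenced from 28 libraries each, 4 per AOM group and 3 per saline group. Per the labels' protocols, the chromatin libraries are biological replicates of pooled samples. Total counts per library, in M (mega) counts, ran from 3.76 to 9.38 M for RNA, with a median of 6.32 M. They ran from 0.99 to 10.39 M for H3K4me3 (median 3.61 M) and from 0.81 to 11.16 M for H3K9ac (median 4.34 M). The group means of the RNA totals lay between 5.41 ± 1.13 M (SD, n = 6) on fish oil and pectin with AOM and 7.21 ± 1.08 M (SD, n = 6) on corn oil and pectin with saline. Those of H3K4me3 were less even, from 3.18 ± 1.72 M (SD, n = 4) on corn oil and cellulose with AOM to 8.51 ± 2.05 M (SD, n = 4) on fish oil and pectin with AOM, which are the groups of the combined diet comparison. Those of H3K9ac lay between 4.04 ± 3.36 M and 6.14 ± 3.70 M (SD, n = 4). Fold changes below are log2 values with their standard errors (SE), and levels are CPM, counts scaled to the same library size, with their standard deviations (SD).

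The comparison of AOM with saline over the 4 diets, 24 RNA libraries against 24, asks what the carcinogen leaves in the colonocytes after 10 weeks. Interferon-stimulated genes were higher after AOM. Mx2, an antiviral GTPase, rose by 1.67 ± 0.23 (SE) to 16.4 ± 14.3 CPM (SD, n = 24) against 4.79 ± 2.22 CPM in saline, Rsad2, an antiviral enzyme, by 1.01 ± 0.16, and Irf9, a transcription factor of the interferon pathway, by 0.45 ± 0.08. Pla2g2a, a secreted phospholipase known in mice as a modifier of intestinal tumor number, rose from 111 ± 28.1 CPM to 283 ± 82.1 CPM (SD, n = 24), a change of 1.35 ± 0.11 (SE) with an adjusted p of 4.26e-11. All 24 AOM libraries lay above the median of the saline group on the same diet for Pla2g2a, Mx2 and Slfn3, a Schlafen family gene that rose by 2.37 ± 0.35.

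Of the 9989 genes tested, 43 were higher and 7 lower after AOM. Of the 20 measured genes of the interferon response and MHC class II list, 9 rose and 0 fell, and 15 rose when adjusted over the list alone. Their mean change was 0.70, with 20 of 20 positive, and the call held with an estimated correlation (adjusted p = 2.13e-07). Olfm4, a marker of intestinal stem cells, rose by 1.79 ± 0.35 and was the single called member of 13 in the list of Wnt targets and crypt stem cell genes, which as a list did not pass. Fabp6, the ileal bile acid binding protein, rose by 1.72 ± 0.30 from 0.703 ± 0.541 to 2.33 ± 2.41 CPM (SD, n = 24), and its list of 8 bile acid response genes did not pass. The defensins Defa8 and Defa9 rose by 1.73 ± 0.33 and 1.68 ± 0.31. Slfn3, Defa8, Defa9 and the Oas genes, of which Oas1a rose by 0.94 ± 0.19, have near-identical relatives, so their counts are uncertain. Acta1, the actin of skeletal muscle, rose by 1.42 ± 0.35. The 5 lower genes named by rule changed less. Lhfpl1 fell by 0.47 ± 0.11, Rragd, an activator of the nutrient sensor mTORC1, by 0.30 ± 0.07, and Arl6ip5, Prcp and the lysosomal protease Ctsh by 0.24 ± 0.06, 0.24 ± 0.06 and 0.23 ± 0.05.

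Of the 22 gene lists, 7 passed camera with the preset correlation in this comparison and 1, the interferon list, also with an estimated one. The immune cell list of 14 genes was higher by a mean of 0.30, with 0 called members and 1 when adjusted over the list alone (adjusted p = 0.145 with an estimated correlation). The list of fatty acid oxidation genes and targets of the nuclear receptor PPAR, 23 genes, was lower by a mean of -0.09 with 0 called members, and oxidative phosphorylation, 25 genes, by a mean of -0.07 with 0 called members (adjusted p = 0.216 and 0.216 with an estimated correlation). Immediate early genes were higher by 0.25, fibroblast and smooth muscle markers by 0.27 and cell cycle genes by 0.09, with 0 called members each (adjusted p = 0.22, 0.457 and 0.574 with an estimated correlation). The calls of Acta1, Arl6ip5, Prcp and Ctsh were lost without the covariate for the animal number, and those of Acta1 and Prcp also without the libraries titled fpa_1405 (fish oil, pectin, AOM) and ccs_1502 (corn oil, cellulose, saline), which stand apart from the other 46. DESeq2 called 91 genes, and 202 were called, 117 higher and 85 lower, with the main axis of variation as a covariate.

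**Figure D1:**
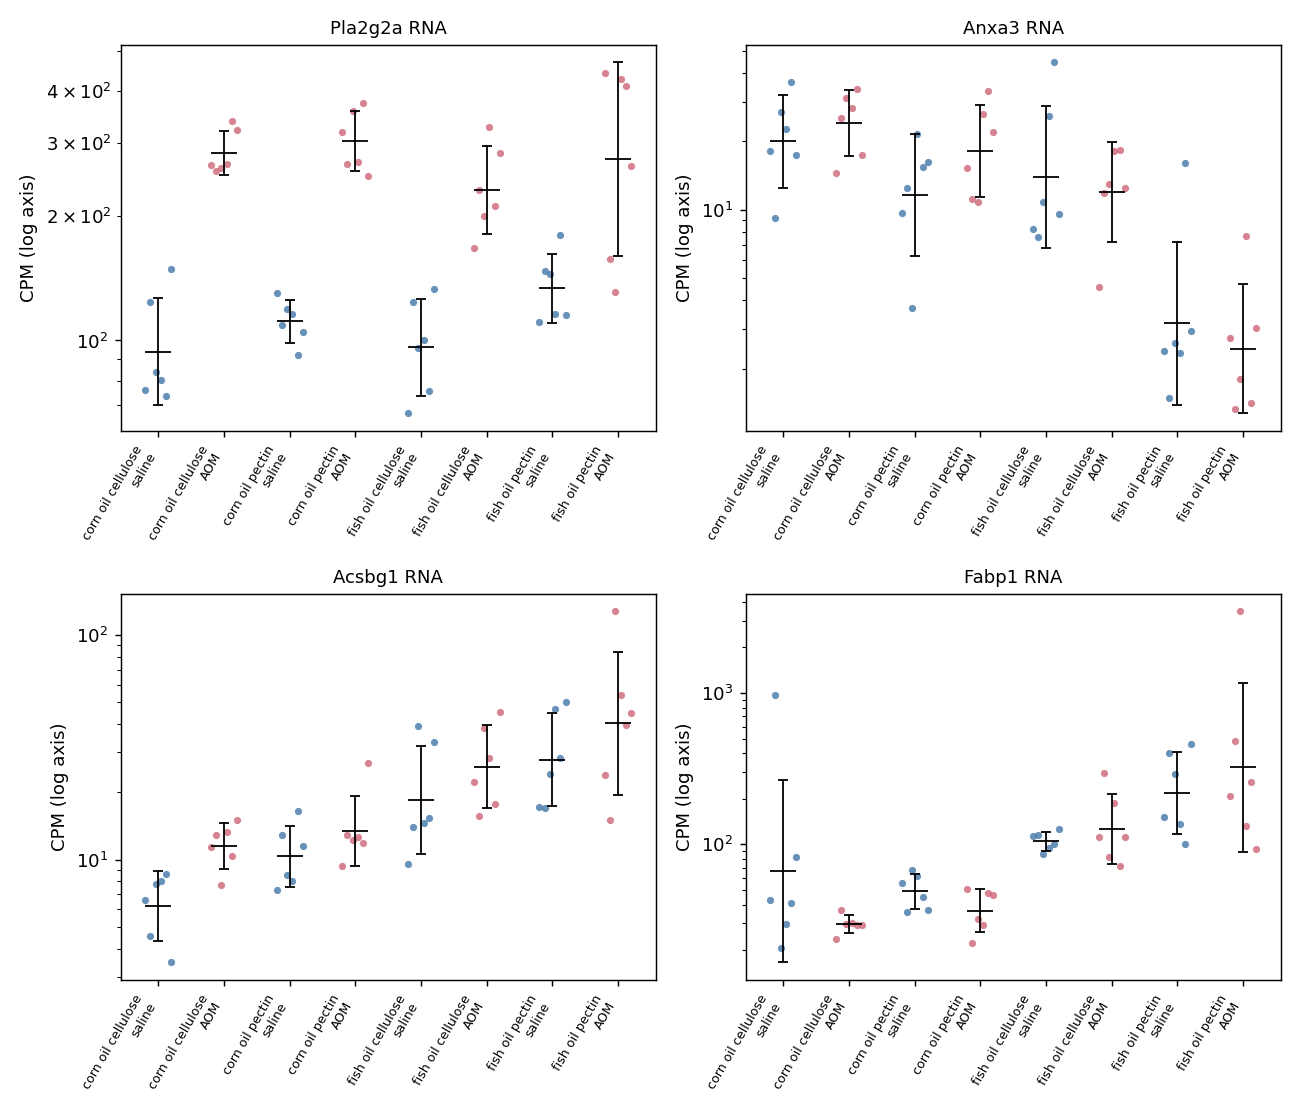
RNA level of Pla2g2a, Anxa3, Acsbg1 and Fabp1 in each of the 48 libraries, in CPM on a log axis, by group. The bar is the mean of the log2 values and its whiskers 1 SD, back-transformed. Pla2g2a lies between 131 and 443 CPM in the fish oil pectin AOM group and between 111 and 180 CPM in the matched saline group, and Fabp1 reaches 3460 CPM in 1 library.

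The oil comparison, 24 fish oil libraries against 24 corn oil libraries, asks what n-3 fatty acids change whatever the fiber and the injection. Genes that handle fatty acids were higher on fish oil. Acsbg1, an acyl-CoA synthetase, rose by 1.60 ± 0.19 (SE) from 10.8 ± 4.68 to 32.6 ± 24.2 CPM (SD, n = 24; adjusted p = 1.42e-06), Acot1, an acyl-CoA thioesterase, by 1.13 ± 0.20, and Slc25a20 and Cpt2, which bring fatty acids into mitochondria, by 0.37 ± 0.07 and 0.32 ± 0.06. Fabp1, a fatty acid binding protein, rose by 1.87 ± 0.34, and Aqp8, a water channel of surface colonocytes, by 1.60 ± 0.27. The Fabp1 level, 319 ± 679 against 79 ± 191 CPM (SD, n = 24), is widened by the libraries titled fpa_1405 at 3460 CPM and ccs_1502 at 971 CPM, and the mean was higher on fish oil in 3 of 4 matched pairs of groups. Without these 2 libraries the change was 2.09. Lower on fish oil were Anxa3, a calcium-dependent membrane-binding protein, by -1.28 ± 0.20 to 9.63 ± 10.0 CPM against 20 ± 8.82 CPM, and the mast cell protease gene Mcpt1 under both of its identifiers, by -1.28 ± 0.29 and -1.03 ± 0.25.

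Of the genes tested, 21 were higher and 25 lower on fish oil. The list of fatty acid oxidation genes and PPAR targets had 5 of 23 measured members higher and 0 lower, and 12 higher when adjusted over the list alone, at a mean of 0.34 (adjusted p = 5.01e-05 with an estimated correlation). Among genes chosen in advance as checks of the diet, Pdk4 rose by 0.79 ± 0.18 and Scd1 by 0.90 ± 0.20. Cpt1a and Fads2 did not pass at 0.23 ± 0.08 and 0.07 ± 0.17, nor did Scd, a close relative of Scd1, at 0.69 ± 0.22. The xenobiotic and antioxidant response list passed with both correlations (17 genes, 13 positive, mean 0.29 and median 0.10, adjusted p = 0.0248 with an estimated correlation). Its called members were Cyp1a1, a monooxygenase induced by aryl hydrocarbons, at 2.74 ± 0.61 with a level of 3.44 ± 4.93 against 1.27 ± 1.62 CPM (SD, n = 24), and the drug efflux pump Abcb1a at 0.86 ± 0.17. Rsad2 was higher by 0.90 ± 0.16 while the interferon list did not pass (1 of 20 called, mean 0.10). Arg2, an arginase, rose by 1.15 ± 0.16. Slc16a12, Fkbp9 and Lhfpl1 fell by 0.68 ± 0.12, 0.64 ± 0.16 and 0.63 ± 0.11.

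Goblet cell markers were lower by a mean of -0.14 over 12 genes, with 0 called and 1 higher and 2 lower when adjusted over the list alone, and immediate early genes were higher by 0.28 over 15 genes with 0 called (adjusted p = 0.235 and 0.178 with an estimated correlation). The immune cell list, which shares a cell origin with Mcpt1, did not pass (mean -0.19). Both calls of Mcpt1 were lost without fpa_1405 and ccs_1502, and 1 of them, like that of Fkbp9, without the animal number covariate. DESeq2 called 86 genes, 73 were called without the 2 libraries, and 337, of which 126 were higher and 211 lower, with the main axis as a covariate.

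The fiber comparison, 24 pectin libraries against 24 cellulose libraries, called 1 gene. Anxa3 was lower on pectin by -1.30 ± 0.20 (SE), at 10.2 ± 9.07 against 19.5 ± 10.3 CPM (SD, n = 24; adjusted p = 0.000691). With edgeR, 262 genes had an unadjusted p under 0.05, where 499 are expected if no gene differs, and DESeq2 called 2 genes. Lists passed camera with the preset correlation in 9 cases and with an estimated one in 0. The largest of these sets, 25 cell cycle genes, was higher by a mean of 0.13 with 23 positive and 0 called (adjusted p = 0.199 with an estimated correlation). Surface colonocyte markers were higher by 0.14, with 1 member called when adjusted over the list alone, and immediate early genes lower by -0.20 (adjusted p = 0.199 and 0.25 with an estimated correlation). The Anxa3 call was lost without the animal number covariate, at an adjusted p of 0.0605.

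Whether the oil acts differently on the 2 fibers was tested as an interaction. With edgeR 0 genes were called, and DESeq2 called 0. The unadjusted p was under 0.05 for 573 genes, and for 1056 with the main axis as a covariate (499 expected if no gene differs). The smallest p-values belonged to Epsti1, an interferon-induced gene, at 1.62 ± 0.37 (SE) and to Anxa3 at -1.70 ± 0.40, each with an adjusted p of 0.354. Anxa3 averaged 2.99 ± 2.39 CPM (SD, n = 6) on fish oil and pectin with AOM, 4.62 ± 5.58 CPM on the same diet with saline and between 13.1 and 25.1 CPM in the other 6 groups.

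The comparison of fish oil with pectin against corn oil with cellulose, both after AOM, is the contrast named in the series title as a diet against the carcinogen. In these 6 libraries against 6, genes of fatty acid metabolism were higher and Anxa3 lower on fish oil and pectin. Anxa3 was at 2.99 ± 2.39 CPM (SD, n = 6) against 25.1 ± 7.66 CPM, a change of -2.75 ± 0.43 (SE; adjusted p = 0.00104). Acsbg1 rose by 2.22 ± 0.39 to 50.8 ± 40.1 CPM, Arg2 by 1.81 ± 0.33 to 52.3 ± 19.9 CPM, Fa2h, which hydroxylates fatty acids, by 1.37 ± 0.28, the acyl-CoA dehydrogenase Acad11 by 0.97 ± 0.19, the acyl-CoA binding protein Dbi by 0.66 ± 0.14 and Slc25a20 by 0.65 ± 0.14. Fabp1 rose by 4.05 ± 0.76 from 29.9 ± 4.16 to 772 ± 1320 CPM (SD, n = 6), of which fpa_1405 alone holds 3460 CPM, and the change was 2.89 without fpa_1405 and ccs_1502. Its lowest library in the fish oil pectin group, at 93.8 CPM, lies above the highest of the corn oil cellulose group, at 36.8 CPM.

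In all, 7 genes were higher and 3 lower. The other 2 lower genes were Lhfpl1, by -1.14 ± 0.23, and the phosphatase Dusp3, by -0.71 ± 0.16. Fatty acid oxidation genes and PPAR targets had 2 of 23 members higher, 11 when adjusted over the list alone, at a mean of 0.67 with 22 positive (adjusted p = 3.88e-05 with an estimated correlation). The group means of that list, in log2 CPM, were 6.88 ± 0.30 and 6.35 ± 0.07 (SD, n = 6). The xenobiotic list also passed with both correlations, at a mean of 0.60 and a median of 0.16 with 12 of 17 positive, 0 called and 3 higher when adjusted over the list alone (adjusted p = 0.0145 with an estimated correlation). The interferon list was lower on fish oil and pectin by a mean of -0.42 with 0 called, surface colonocyte markers higher by 0.41 with 5 called when adjusted over the list alone, and goblet cell markers lower by -0.29 (adjusted p = 0.0845, 0.0847 and 0.0845 with an estimated correlation). Cell cycle genes were higher by 0.35, with 25 of 25 positive and 0 called (adjusted p = 0.172 with an estimated correlation). Fitting the 2 groups alone left 0 calls, with 199 genes at an unadjusted p under 0.05, so the calls rest on the spread pooled over 8 groups. In the fit over 8 groups 429 genes reached that unadjusted p, where 499 are expected if no gene differs. With the main axis of variation as a covariate 1229 did. DESeq2 called 49 genes, the model without the animal number covariate 32 and the model with the main axis of variation 89, and the calls of Dbi and Dusp3 were lost without fpa_1405 and ccs_1502. Without fpa_1403 as well, those of Fa2h, Acad11 and Slc25a20 were also lost (adjusted p = 0.0785, 0.0697 and 0.281).

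**Figure D2:**
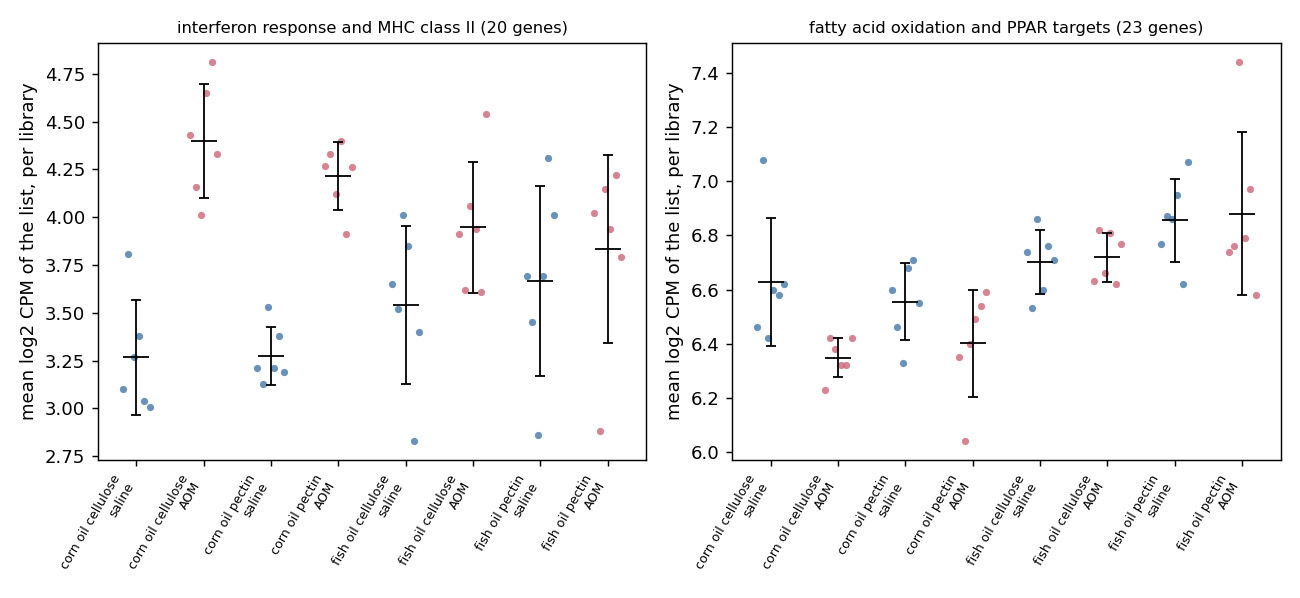
Mean log2 CPM per library of the 20 interferon and MHC class II genes and of the 23 fatty acid oxidation genes and PPAR targets, by group, with the group mean and 1 SD (n = 6). The interferon genes average 4.40 after AOM and 3.27 after saline on corn oil and cellulose, and 3.83 and 3.67 on fish oil and pectin.

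On corn oil and cellulose alone, AOM against saline asks for the response without fish oil or pectin, in 6 libraries against 6. Interferon-stimulated genes were among those that rose. Mx2 rose by 2.64 ± 0.49 (SE) to 28.2 ± 23.5 CPM against 4.15 ± 1.32 CPM (SD, n = 6), Ly6e, an interferon-induced surface protein, by 1.82 ± 0.36, Oasl2, an antiviral protein, by 1.8 ± 0.33, Rsad2 by 1.58 ± 0.33 and Irf9 by 0.76 ± 0.16. Pla2g2a rose by 1.51 ± 0.23 from 97.8 ± 31.4 to 285 ± 35.7 CPM (SD, n = 6; adjusted p = 0.000575). For each of these 6 genes, 6 of 6 AOM libraries lay above the saline median.

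There were 9 higher and 0 lower genes. Of the 20 interferon and MHC class II genes 3 rose, 12 when adjusted over the list alone, with a mean of 1.15 and 20 of 20 positive (adjusted p = 5.03e-07 with an estimated correlation). Fatty acid oxidation genes and PPAR targets were lower by a mean of -0.36 with 0 of 23 positive and 0 called (adjusted p = 0.0121 with an estimated correlation). Oxidative phosphorylation was lower by -0.17 and surface colonocyte markers by -0.23, and immune cell and immediate early genes were higher by 0.27 and 0.29, with 0 called in each (adjusted p = 0.0845, 0.492, 0.492 and 0.492 with an estimated correlation). Fitting the 2 groups alone left 0 calls, with 190 genes at an unadjusted p under 0.05. In the fit over 8 groups 277 genes reached that unadjusted p, where 499 are expected if no gene differs. With the main axis of variation as a covariate 720 did. DESeq2 called 16 genes, the model with the main axis 22, and the Irf9 call was lost without fpa_1405 and ccs_1502.

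Whether fish oil with pectin changes the response to AOM was tested as the difference of the 2 AOM effects. No single gene passed with edgeR, with 0 calls and 1 gene by DESeq2. The unadjusted p was under 0.05 for 184 genes, and for 428 with the main axis as a covariate (499 expected if no gene differs). The interferon list did pass. Its response was smaller on fish oil and pectin by a mean of -0.91 over 20 genes, 0 of them positive, with 2 lower when adjusted over the list alone (adjusted p = 0.00315 with an estimated correlation). These 2 were Irf9, at -0.74 ± 0.23 (SE), and RT1-Ba, an MHC class II gene with close relatives whose counts are uncertain, at -1.51 ± 0.45, each with an adjusted p of 0.999 over all genes by edgeR. Part of the difference lies in the saline groups, where the list averaged 3.67 ± 0.50 log2 CPM on fish oil and pectin and 3.27 ± 0.30 on corn oil and cellulose (SD, n = 6). After AOM these means were 3.83 ± 0.49 and 4.40 ± 0.30. Fatty acid oxidation genes and PPAR targets differed by a mean of 0.49 with 23 of 23 positive and 1 called when adjusted over the list alone (adjusted p = 0.0888 with an estimated correlation), and this list no longer passed without fpa_1405 and ccs_1502 (adjusted p = 0.109 with the preset correlation). Fibroblast and smooth muscle markers differed by a mean of -0.57 over 7 genes, circadian clock genes by -0.27, immediate early genes by -0.38 and cell cycle genes by 0.29, each passing with the preset correlation only (adjusted p = 0.205, 0.205, 0.475 and 0.511 with an estimated correlation). The self-test recovered 20.9% of simulated 2-fold and 65.2% of 4-fold differences in this comparison, so moderate differences of single genes were mostly not detectable here.

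H3K4me3 differed with AOM more than any other comparison of a mark. Of 33539 regions tested, 2246 were lower and 361 higher in 16 AOM libraries than in 12 saline libraries, and the median log2 change of all regions was 0.14. The number of higher regions depends on the model, at 175 with library totals alone and 810 with the first axis of variation as a covariate, against 2141 and 2136 lower ones. Regions that hold an annotated transcript start made up 62.3% of the lower ones, 5% of the higher ones and 23% of those not called. The median change was -0.16 over 8531 regions holding a start and 0.26 over the other 25008. The lower regions had a median change of -0.56 and the higher ones of 0.64. Of the total H3K4me3 counts, 39.3 ± 8.7% (SD, n = 16) fell in start regions in AOM libraries and 45.5 ± 7.8% (SD, n = 12) in saline libraries, against 17.9% in the IgG control.

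Among called regions with a mean log2 CPM of at least 2, the lower ones with the largest change were nearest to Dstn, which codes for an actin-depolymerizing protein, at -2.48 ± 0.45 (SE), the transcription factor gene Usf2 at -1.78 ± 0.28, Pou3f1, another transcription factor gene, at -1.73 ± 0.33, and Urod, an enzyme of heme synthesis, at -1.73 ± 0.28. The Dstn region (chromosome 3, 132531955 to 132533062) held 4.94 ± 4.98 CPM (SD, n = 16) after AOM and 23 ± 13.5 CPM (SD, n = 12) after saline. The Usf2 region (chromosome 1, 85990991 to 85992697) held 10.3 ± 6.50 and 33.8 ± 17.2 CPM. All 16 AOM libraries lay below the median of the saline group on the same diet at these 4 regions, of which the Pou3f1 region holds a transcript start. Above the same limit, the higher regions with the largest change were nearest to Lrif1 at 1.15 ± 0.32, Gpm6a at 1.05 ± 0.30, Snx3 at 1.04 ± 0.29 and Zfp868 at 0.99 ± 0.29, at levels of 5.48 to 6.25 CPM after AOM, and none of these 4 holds a start. Over all called regions, the changes reached -3.55 and 2.30. Against the IgG control, the median log2 ratio of the levels was 1.17 over the lower regions and -0.32 over the higher ones, so the higher regions lie on the whole at or below background. This is not particular to them: the median was 0.04 over the regions not called. It was 1.19 over regions holding a start and -0.23 over the others. Coordinates are as the tables give them, for which the submitters' notes name the builds rn4 and rn5 without saying which applies. AOM libraries carry the numbers 1 to 16 and saline libraries 17 to 28, so the order of the libraries and the injection cannot be separated. Leaving out 1 library at a time gave 976 to 3414 calls, and 4 saline libraries moved the count by over 1.5 times. With the first 2 axes of variation among the libraries as covariates edgeR called 0 regions, and the change near Dstn was -1.03. In that fit 1874 regions had an unadjusted p under 0.05, where 1677 are expected if no region differs. AOM accounts for 37.4% of the second of these axes, so that model also removes part of the difference it tests.

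**Figure D3:**
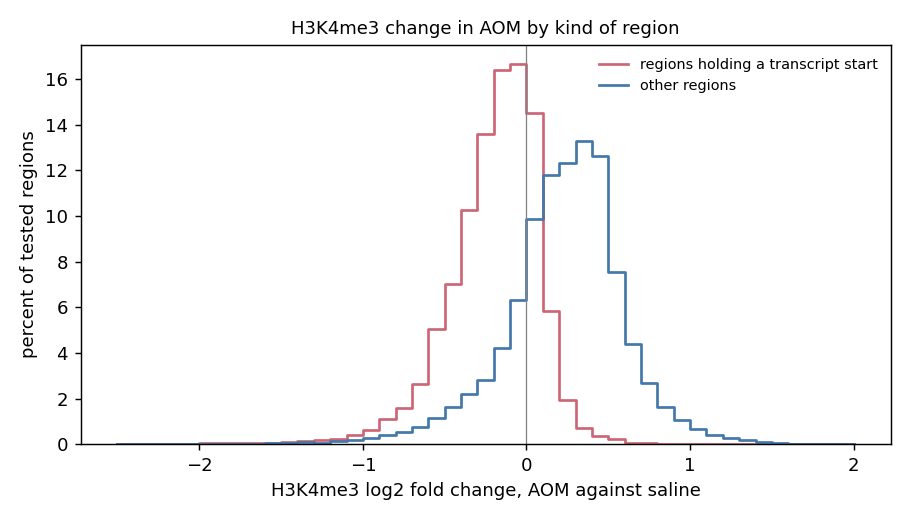
Distribution of the log2 fold change of H3K4me3, AOM against saline, over the 8531 regions that hold a transcript start and the 25008 that do not. The medians are -0.16 and 0.26.

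For H3K4me3, edgeR called 0 regions in the other 6 comparisons. The unadjusted p was under 0.05 for 4016 regions by oil, 1241 by fiber, 371 in the oil by fiber interaction, 838 for fish oil pectin against corn oil cellulose in AOM, 4251 for AOM on corn oil and cellulose and 358 in the AOM by diet interaction. If no region differs, 1677 are expected, which only the counts by oil and for AOM on corn oil and cellulose exceed. Which counts exceed it depends on the model. With the first axis of variation as a covariate they were 773 by oil, 2786 by fiber and 2295 for the combined diet. They were then 4790 for AOM on corn oil and cellulose, 970 in the oil by fiber and 1043 in the AOM by diet interaction. DESeq2 called 15 regions, all lower, for AOM on corn oil and cellulose and 0 in the other 5. Without library 17 edgeR called 270 regions for AOM on corn oil and cellulose. The region with the smallest p for both pectin and the combined diet holds the start of Hes5, a target of Notch signaling. It stood at 15.0 ± 4.33 against 8.77 ± 3.99 CPM (SD, n = 14) by fiber and at 14 ± 3.25 against 4.14 ± 1.33 CPM (SD, n = 4) for the combined diet (adjusted p = 0.632 and 0.312).

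H3K9ac was higher after AOM in 4 of 53741 regions and lower in 0. The region with the largest change overlaps Cdkn1a, the cell cycle inhibitor p21 and a target of p53. It rose by 1.68 ± 0.23 (SE) from 1.68 ± 0.823 CPM (SD, n = 12) to 5.17 ± 1.76 CPM (SD, n = 16; adjusted p = 0.000137), and 14 of 16 AOM libraries lay above the highest saline library. The IgG control held 7.28 CPM there, above both groups, and the RNA of Cdkn1a differed by 0.09 (adjusted p = 0.999). The other regions were nearest to Mir34a, a microRNA gene that p53 activates, at 0.54 ± 0.10, to Prss16 at 0.66 ± 0.13 and to Acpl2 at 0.39 ± 0.07. The regions lie 19897, 11236 and 28710 bp from these genes. Their levels after AOM were 15.5 ± 2.52, 12.3 ± 2.41 and 50.2 ± 4.32 CPM (SD, n = 16) against 14.6, 8.32 and 26 CPM in the IgG control. Cdkn1a and Mir34a fall outside the rule for named regions and were chosen after their values were seen. Leaving out 1 library at a time gave 1 to 5 calls, and DESeq2 called 6. With edgeR the unadjusted p was under 0.05 for 2633 regions, where 2687 are expected if no region differs. The H3K9ac libraries carry the same numbers as the H3K4me3 ones, 1 to 16 for AOM and 17 to 28 for saline. Their order and the injection cannot be separated here either.

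In the other 6 H3K9ac comparisons edgeR and DESeq2 called 0 regions. With edgeR, 2035 regions had an unadjusted p under 0.05 by oil, 1975 by fiber, 1626 in the oil by fiber interaction, 2116 for the combined diet in AOM, 2994 for AOM on corn oil and cellulose and 1448 in the AOM by diet interaction. If no region differs, 2687 are expected, which only the count for AOM on corn oil and cellulose exceeds. The smallest p-values by oil belonged to regions nearest to Cebpb, at 25 ± 5.02 against 18.4 ± 2.54 CPM (SD, n = 14), and at the start of Scd, at 100 ± 10.8 against 79.8 ± 9.36 CPM (adjusted p = 0.797 and 0.899). At the start of Anxa3, H3K9ac was at 8.07 ± 0.638 CPM on fish oil and pectin and 13.7 ± 2.44 CPM on corn oil and cellulose after AOM (SD, n = 4; adjusted p = 1).

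At the genes called in RNA, both marks moved with RNA on balance. This asks whether histone marks differ where transcription does, with a mark's change counted as positive when it has the sign of the RNA change. For the oil effect the mean signed change was 0.10 for H3K4me3, with 29 of 43 genes in the direction of RNA, and 0.06 for H3K9ac, with 34 of 42 genes (fry with limma, adjusted p = 0.00172 and 0.00172 over the 6 results of this kind). For fish oil with pectin against corn oil with cellulose in AOM it was 0.35 for H3K4me3 with 5 of 9 genes and 0.23 for H3K9ac with 7 of 8 genes (adjusted p = 0.0101 and 0.00192). For the fiber effect the set is Anxa3 alone, at 0.39 and 0.31 in the direction of its RNA (adjusted p = 0.00978 and 0.00237). The genes of the combined diet and fiber sets all belong to the oil set and the comparisons share libraries, so they are not separate evidence. The libraries of each group carry consecutive numbers in both marks. In the combined diet comparison their order and the diet therefore cannot be separated. Random sets of genes with the same signs averaged 0.01 ± 0.025 for H3K4me3 and 0 ± 0.013 for H3K9ac by oil (SD, 10000 draws). For the combined diet they averaged 0.004 ± 0.083 and 0.003 ± 0.063. With the mean over all regions of a gene in place of its most abundant region, the changes for the oil effect fell to 0.0415 for H3K4me3, with 24 genes in the direction of RNA, and 0.0394 for H3K9ac, those for the combined diet in AOM no longer passed, and that of H3K9ac for fiber had the opposite sign. These changes are small against those of RNA, and no single region of either mark was called by edgeR in these 3 comparisons.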

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

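The tests of the order of the library numbers and of another position along the colon and the fit with 2 axes of variation were chosen after the result was seen.

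H3K4me3 was lower after AOM in 2246 regions, of which 62.3% hold a transcript start. A smaller share of reads near starts in AOM libraries, 39.3 ± 8.7% (SD, n = 16) against 45.5 ± 7.8% (n = 12), stays open as the whole cause. With that share as a covariate, 73.6% of the regions stayed lower, and their median change went from -0.56 to -0.42 with a median SE of 0.14 and 0.12. The share is taken from the same counts and enters as a single linear term, so this fit cannot decide. The lower regions had a median log2 ratio to the IgG control of 1.17. The regions not called, at a ratio of 0.04, had a median change of 0.16. The same covariate changed the balance of the calls, from 2246 lower and 361 higher to 1903 lower and 1063 higher. Lower transcription of the genes concerned is argued against by a mean RNA change of 0.035 ± 0.15 (SD) over 1218 genes with a lowered start region. The order of the libraries stays open and cannot be told apart from AOM, since 0 AOM libraries are numbered above the lowest saline number, and with the first 2 axes of variation as covariates 0 regions were called (AOM accounts for 37.4% of the second axis). Of 60 splits of the libraries, 3, the real one included, gave as many calls, so chance cannot be excluded: the real split gave 2607 and the highest other 11945, which points to a structure among the libraries.

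The RNA libraries fpa_1405 and ccs_1502 lie apart from the other 46, at 4.1 and 4.37 SD on the second axis of variation. Both were far lower than the median of the others in Hoxb13, by -6.44 and -6.92, and Hoxd13, by -7.09 and -6.65, and higher in Hoxb7, by 4.82 and 5.33. For small intestinal tissue, 11 measured genes abundant in the small intestine did not rise as a set. Of these, 27.3% were over 2-fold higher in each library, and the median difference was 0.02 and 0. A gene present in these libraries alone would fail the low-count filter. The test thus covers only genes that other libraries also express, and small intestinal tissue stays open. Other genes that are high in the small intestine were far higher, with Fabp1 by 5.48 and 3.65, Reg3g at 184 and 1940 CPM against a median of 0.572 CPM in the others and Reg3b at 49.2 and 994 against 0.151 CPM. Another position along the colon is a candidate explanation, since Hox genes of low paralogue number were higher and those of high number lower (Spearman rho -0.75 and -0.81 over 8 genes). This was tested on the libraries that raised it, no position is given in the labels, and a mix-up with other tissue was not tested.

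The first axis of RNA variation holds 65% of the variance, and the 8 groups account for 4.9% of it. Library size may contribute, but its Pearson r with the axis, -0.498 over 48 libraries, fell short of the size of 0.5 set in advance, so this stays open (permutation p = 0.00017, adjusted over 2 relations 0.00034; Spearman rho -0.41, permutation p = 0.0046), and r was -0.34 without the 2 libraries farthest in size. Within the libraries with first digit 1 and 2 of the animal number it was -0.56 and -0.41. A few genes taking most of the counts also stay open, at an r of -0.207 ± 0.14 (SE; permutation p = 0.16), which lies within the 0.3 set in advance but not by more than its spread, with -0.34 and -0.02 within the first digits 1 and 2. Other cell types stay open, as the lists of fibroblast, immune, endothelial and enteroendocrine markers all moved 1 way but by as little as -0.07 per SD of the axis. Goblet cell and surface colonocyte markers, which a larger share of other cells would move the other way, moved the same way (medians -0.26 and -0.20, with 5 of 12 and 4 of 15 positive), but with members going both ways this does not decide. No biological explanation other than cell types was tested.

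Single libraries lay far from the other libraries of their group in 5 of 72 tests, and chance alone gives about 1 in 20 groups. Fabp1 in ccs_1502 was at 9.92 log2 CPM, with the next library at 6.36. Acsbg1 in cpa_2210 (corn oil, pectin, AOM) was at 4.77, with the next at 3.73. Anxa3 in fca_1301 (fish oil, cellulose, AOM) was at 2.29, below the next at 3.61, and in fps_2805 (fish oil, pectin, saline) at 4.02, above the next at 1.69. H3K9ac at Cdkn1a in library 1 of corn oil cellulose AOM was at 2.9, above the next at 2.4.

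Effects that differ between groups by the preset correlation of camera were seen in 11 cases. In the difference of the AOM effects between fish oil with pectin and corn oil with cellulose, the interferon list differed by a mean of -0.91, fatty acid oxidation by 0.49, cell cycle by 0.29, fibroblast markers by -0.57, circadian clock genes by -0.27 and immediate early genes by -0.38. With an estimated correlation the interferon list alone passed (adjusted p = 0.00315), and the others had adjusted p of 0.0888, 0.511, 0.205, 0.205 and 0.475. In the difference of the oil effects between pectin and cellulose, fatty acid oxidation differed by 0.26, goblet cell markers by -0.36, enteroendocrine markers by 0.23, immediate early genes by -0.58 and the unfolded protein response by -0.26, and with an estimated correlation 0 passed (adjusted p = 0.818, 0.237, 0.799, 0.512 and 0.639).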

How the results depend on the processing

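The fits with 1 or 2 axes of variation as covariates and those without 2 or 3 RNA libraries were chosen after the result was seen. Across the alternatives 0 of the 63 named values reversed. DESeq2 kept all 63, the low-count filter left out lost 2 (Dusp3 and Irf9), RLE size factors lost 3 (Prcp, Irf9 and H3K9ac near Prss16), and the cause of each was not tested. Of the 51 named RNA calls, 7 were lost without the animal number covariate, 7 without 2 libraries and 9 without 3, and 0 with 1 or 2 axes as covariates. Fitting the groups of a contrast alone lost 16 of 16. The first axis lost 3 of 8 named H3K4me3 calls and 1 of 4 for H3K9ac, and 2 axes lost 8 of 8 and 0 of 4.

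Counts of calls for RNA moved by over 1.5 times as follows. DESeq2 called 91 genes for AOM, 86 for oil, 2 for fiber, 49 for fish oil pectin against corn oil cellulose in AOM, 16 for AOM on corn oil cellulose and 1 for AOM by diet, and 15 H3K4me3 regions for AOM on corn oil cellulose. Without the animal number covariate 0 genes were called for fiber and 32 for the combined diet. Fitting the groups of a contrast alone, which uses fewer samples, called 0 for the combined diet and 0 for AOM on corn oil cellulose. Without fpa_1405 and ccs_1502, oil had 73 and fiber 4, and without fpa_1403 as well AOM had 86, oil 75 and fiber 5. With the first axis as covariate AOM had 202, oil 337, the combined diet 89 and AOM on corn oil cellulose 22. With the first 2 axes these were 320, 495, 52 and 37, fiber had 15, H3K4me3 had 0 for AOM and 1 for oil, and H3K9ac had 8 for AOM. The cause was not tested.

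Leaving out 1 mark library at a time gave 976 to 3414 H3K4me3 regions for AOM (976 without library 19, 1128 without 27, 1436 without 20, 1539 without 25), 0 to 270 for AOM on corn oil cellulose (270 without library 17), and 1 to 5 H3K9ac regions for AOM, where 16 of the 28 libraries moved the count by over 1.5 times. The other mark comparisons stayed at 0. Of the named regions, the H3K9ac calls near Prss16, Mir34a and Acpl2 were lost in 23, 17 and 14 of the 28 fits and that at Cdkn1a in 0, and the H3K4me3 calls near Lrif1, Gpm6a, Snx3 and Zfp868 in 5, 5, 5 and 8. The mean signed change at RNA-called genes stayed within 0.0825 to 0.111 and 0.304 to 0.468 for H3K4me3 by oil and fiber, 0.29 to 0.411 for the combined diet, and 0.0528 to 0.0682, 0.26 to 0.357 and 0.157 to 0.282 for H3K9ac, and passed each time. With the mean over all regions of a gene it fell from 0.0969 to 0.0415 for H3K4me3 and from 0.0619 to 0.0394 for H3K9ac by oil, still passing. It was 0.288 for H3K4me3 and 0.0822 for H3K9ac for the combined diet, no longer passing, and -0.0471 for H3K9ac by fiber, reversed. The cause was not tested.

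With an estimated correlation between genes, camera called 1 list for AOM, 2 for oil, 0 for fiber, 0 for oil by fiber, 2 for the combined diet, 2 for AOM on corn oil cellulose and 1 for AOM by diet. With the preset correlation, the 5 lists called for oil by fiber fell to 3 without the animal number covariate, 3 with the first axis and 2 without fpa_1405 and ccs_1502. The cause was not tested. Median log2 changes of all H3K4me3 regions for AOM were 0.136, 0.091 with library totals alone and 0.097 with RLE. No paired analysis was possible because the groups compared share no animal or library numbers. What depth limits was not tested apart from the spread between libraries. At 4 against 4 libraries edgeR recovered 10.4% of simulated 2-fold changes for H3K4me3 and 43.3% for H3K9ac, at median totals of 3.61 and 4.34 M counts and a biological coefficient of variation of 32.3% and 16.5%.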

Other observations

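The tests of the p53 list in H3K9ac and of the oil on each fiber and the comparison of the marks with random genes were chosen after the result was seen.

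The marks at the genes called in the RNA AOM effect were a question added after the data were seen, with the bounds for its answer set before its result was seen. H3K4me3 moved with RNA by a mean signed log2 change of 0.153, with 31 of 41 genes in the direction of RNA (fry with limma, unadjusted p = 5.82e-05), by 0.122 to 0.163 with 1 library left out and by 0.116 with library totals alone. Random sets of genes tested in RNA and not called, given the same signs, averaged -0.112 ± 0.040 (SD, 10000 draws), since the most abundant regions of these 8725 genes were lower in AOM by a mean of -0.159. H3K9ac also moved with RNA, by 0.0816 with 31 of 40 genes (fry with limma, unadjusted p = 5.54e-05), where random sets averaged -0.013 ± 0.015 (SD). The size falls short of the 0.1 set in advance for a clear answer, at 0.0648 with the mean over all regions of a gene and 0.105 with library totals alone, so whether H3K9ac follows RNA by that much stays open.

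H3K9ac rose after AOM at Cdkn1a and in a region 19897 bp from Mir34a, both targets of p53, and a candidate explanation is a gain at p53 targets as a group. At the most abundant region of each of the other 14 genes of the p53 list, the mean H3K9ac change was 0.001 ± 0.15 (SD). Of these genes 5 were positive, the highest being Phlda3 at 0.46. This argues against a shared gain at the most abundant regions. The called region at Cdkn1a lies below the IgG control and that near Mir34a lies far from its gene. Weaker or distant regions of the other p53 targets were not tested, so a gain there stays open. The call near Mir34a was also lost in 17 of the 28 fits with 1 library left out, and that at Cdkn1a in 0.

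The smaller interferon response to AOM on fish oil and pectin may come from the oil. The AOM effect on the 20 genes of the list was lower with fish oil by a mean log2 difference of -0.75 on cellulose (17 genes negative, adjusted p = 0.0767 with an estimated correlation) and -0.86 on pectin (18 genes negative, adjusted p = 0.0176). On cellulose it misses the threshold, so whether the oil lowers the response on both fibers stays open. On cellulose the list averaged 3.54 log2 CPM with fish oil against 3.27 with corn oil after saline, and 3.95 against 4.40 after AOM. On pectin it averaged 3.67 against 3.28 after saline and 3.83 against 4.22 after AOM. A higher saline level and a lower AOM level with fish oil thus both enter the difference.

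Other splits of the libraries, 60 per result with the real one, were compared with the real groups. For the RNA oil effect 1 split, the real one, gave as many calls (real 46, highest other 2). It was also 1 for fish oil with pectin against corn oil with cellulose in AOM (10 and 1). The same held for AOM on corn oil and cellulose (9 and 0) and for H3K9ac by AOM (4 and 0). These shares are under the bound of 0.05 set in advance, but 60 splits are too few to exclude chance. The RNA calls of the 2-group comparisons also fell to 0 when those groups were fitted alone. For H3K9ac the order of the libraries and AOM cannot be told apart. For fiber 2 splits gave as many calls (1 and 1). That share is also under the bound, but the count is a single gene and 1 other split called as many. The call was lost without the animal number covariate (adjusted p = 0.0605). For the RNA AOM effect 3 splits gave as many (50 and 3584), so chance cannot be excluded, and the highest points to a structure of the samples. For the number of lists called, 6 splits gave as many for AOM (7 and 10), 35 for oil (4 and 11), 4 for fiber (9 and 10) and 23 for AOM on corn oil and cellulose (6 and 13), so chance cannot be excluded, while 2 did for the combined diet in AOM (9 and 10). That share too is under the bound of 0.05 set in advance, but 1 other split called more lists than the real one, and 2 of the 9 lists passed with an estimated correlation. Splits were not drawn for the interactions.

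The deposited comparisons of the authors, per the file headers, hold 92 genes under an adjusted p of 0.05 for saline against AOM, 94 for n-3 oil, 2 for pectin, 63 for the combined diet in AOM, 24 for AOM on corn oil and cellulose and 0 for oil by fiber. They include all 50, 46, 1, 10 and 9 genes called here, in the same direction. For the marks they hold 5512, 2, 5, 4, 143 and 0 H3K4me3 entries and 29, 14, 0, 0, 0 and 6 H3K9ac entries in the same order.

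The lists of cholesterol synthesis, Wnt targets and crypt stem cell genes, p53 targets, inflammation, endothelial cells and histone enzymes were called in 0 of the 7 RNA comparisons.

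Some lists passed camera with the preset correlation and not with an estimated one, and are not described above. By fiber these were fatty acid oxidation at a mean of 0.08, fatty acid synthesis at 0.11, short chain fatty acid uptake and sensing at 0.05, xenobiotic response at 0.25 (median 0.06), bile acid response at 0.17 and goblet cell markers at -0.11, with 0 called members each. For fish oil with pectin against corn oil with cellulose in AOM they were fatty acid synthesis at 0.37, bile acid response at 0.45 and circadian clock genes at -0.21, also with 0 called members each.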
